A study of Mus musculus with 9 samples.

How the data were processed

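Poly(A) RNA of 9 adult mouse hearts was sequenced, 5 from wild-type mice and 4 from mice labelled as germline Parkin knockouts, all on a C57BL/6J background. Per the labels' protocols, RNA was taken with Trizol from flash-frozen ventricular apices, although the tissue label reads whole heart. Polyadenylated RNA was bound to oligo(dT), fragmented chemically and made into single-end libraries that do not keep strand. Reads of overlapping or antisense genes therefore cannot be told apart.

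The authors deposited a table of read counts per gene, with 1 column per heart and 23457 rows. The authors deposited a second table of FPKM values (fragments per kilobase, scaled to sequencing depth) for the same hearts, with 23369 rows. Per the submitters' processing notes, the tools were Bowtie2, TopHat, TopHat2 2.0.10, HTSeq, DESeq, edgeR and Cufflinks 2.1, and the genome build was mm10. The notes give neither the order nor the role of each tool. The annotation, the strand setting and which reads the depth in FPKM covers are not given in the sources used here. The counts were used as deposited.

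Of the rows of the count table, 21962 matched a gene symbol of RefSeq on GRCm38.p6 or of GENCODE vM21 directly and 1294 through a synonym. A further 37 were Ensembl identifiers of mitochondrially encoded genes, and 164 were not matched. Among all rows, 27 carried calendar dates in place of symbols, as spreadsheet software writes for some gene families. Those names were not resolved, and 2 of them stood on 2 rows each. Coordinates are from GRCm38, the assembly that mm10 names.

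The total per heart ranged from 4415183 to 20827699 assigned reads. The FPKM table carries no depth of its own. Intervals for shares of reads are 95% Wilson intervals and cover counting error only.

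Genotypes were compared with edgeR 4.0.16 in R 4.3.3, with TMM normalisation, its default expression filter by group (at least 10 reads, 15 in total) and quasi-likelihood F tests without a replicate term. P-values were adjusted by Benjamini and Hochberg, and the threshold was 0.05. CPM denotes read counts relative to the TMM-scaled library size, in the usual CPM unit, and log2 fold changes are the labelled knockout over wild type, with standard errors derived from the F statistic. A total of 36 gene lists, fixed before the data were examined, was tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01. Of these, 34 had at least 3 measured members. Camera with an estimated correlation and fry were run beside it. FPKM values were tested with limma-trend on log2(FPKM + 1) for genes with a mean of at least 0.5, so those fold changes understate the change of low genes. Measures with 1 value per heart were compared by two-sided exact permutation tests over all 126 splits, 7 measures forming 1 family.

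Named genes followed a rule fixed before the data were examined. It took Pink1, Mfn1, Mfn2, Nnt, Nppa, Nppb, Myh7 and 5 sex-linked genes whatever their values. It added the 12 genes with the largest rise and the 12 with the largest fall among called genes with a mean of at least 1 CPM and groups that did not overlap. From each list it took up to 4 called members with the smallest p, or 2 members as values where none was called. Btbd9 and Glo1 were chosen after their values were seen. Some genes that the rule took, and a planned test of 1 region, are not reported here.

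Alternatives fixed beforehand were RLE and upper-quartile factors, no filter, a mean of at least 1 CPM, DESeq2 1.42.0, limma-voom with quality weights, each heart left out in turn, the replicate number as a block, a threshold of 0.1, and FPKM pseudocounts of 0.1 and 0.01 with other filters. Alternatives chosen after seeing the data were a correction for GC content and length, omission of mitochondrially encoded genes and Rn45s, omission of the 2 shallowest wild-type hearts, nuclear counts thinned to 1845431 reads per heart, and median-centred FPKM. The correction fitted lowess curves (span 0.3) of each heart's log2 deviation against transcript GC content, then length, and used them as offsets. It had values for 99.2% of tested genes, and it also removes any biological difference that follows GC content or length.

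The procedures were tested on simulated counts for 12542 genes in the design of 4 against 5 hearts, with 200 genes changed. Without a simulated GC trend, edgeR recovered 29.0% of genes changed 1.5-fold, 77.5% of those changed 2-fold and 95.5% of those changed 4-fold, and 4.20% of its calls were unchanged genes. When each simulated heart was given the GC slope of the real one, 95.8% of edgeR's 3652 calls were unchanged genes. With the correction the share was 5.48% of 146 calls. The simulated trend was linear in GC content, and no length trend was simulated. The share of unchanged genes among corrected calls in the real hearts therefore cannot be read from it. No pair of hearts held identical values, and hearts of 1 group differed by 5.20 to 119 times the variance that counting alone gives.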

Results

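Hearts of mice labelled as germline Parkin knockouts were compared with wild-type hearts. In the study the mouse hearts were an adjunct to work on Drosophila heart tubes, and the comparison asks which cardiac transcripts differ with the genotype. Each library came from 1 heart, 5 wild-type (WT) and 4 labelled knockout (KO). Assigned reads came to 20827699, 4415183, 4655742, 14201590 and 11252463 in WT hearts 1 to 5 and to 15660129, 13180685, 15777844 and 11637206 in KO hearts 1 to 4.

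The hearts are called labelled knockouts throughout, and every direction given rests on those labels. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had reads in each of the 9 hearts, with Ddx3y at 68 to 645 reads, and Xist, the transcript of the inactive X chromosome, had 2 to 21. Ddx3y was lower in the labelled knockouts by edgeR (log2 fold change -1.17 ± 0.19, adjusted p = 1.54e-04), as was Eif2s3y (-0.93 ± 0.19, adjusted p = 9.2e-04). With GC and length trends removed these were -0.28 and -0.18 and no longer passed the test (adjusted p = 0.184 and 0.560), while Uty passed as higher (0.78, adjusted p = 0.021).

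**Figure D1:**
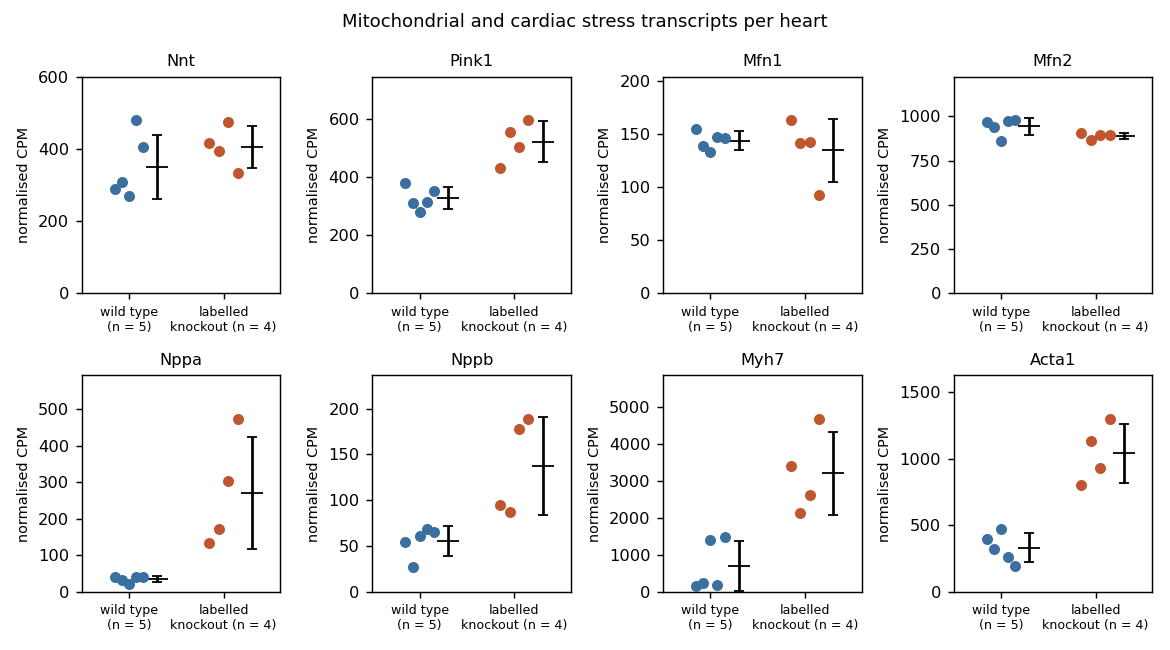
Normalised CPM (linear axis from 0) of Nnt, Pink1, Mfn1, Mfn2, Nppa, Nppb, Myh7 and Acta1 in each of the 9 hearts; points are hearts, bars the mean ± SD of 5 wild-type and 4 labelled knockout hearts. Nnt overlaps between the groups, while each labelled knockout heart lies above each wild-type heart for Nppa, Nppb, Myh7 and Acta1.

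The transcriptomes differed widely. Of 12640 genes tested, 6503 (51.4%) passed the threshold, 3313 higher and 3190 lower in the labelled knockouts, and 990 rose and 1277 fell at least 2-fold. In 41.6% of tested genes the groups did not overlap, where chance gives 1.59%. The fold change followed base composition. Across genes, which are not independent replicates, it correlated with transcript GC content with a Spearman rho of 0.61. The median log2 fold change was -0.59 in the 25% of genes with the lowest GC content and 0.59 in the 25% with the highest. Each heart's slope against GC content separated the groups, from -0.40 to -0.19 log2 units per 10 percentage points in wild type and from 0.17 to 0.65 in the labelled knockouts (exact permutation p = 0.0079, the smallest that 126 splits can give; adjusted p = 0.019). The slope against transcript length separated the groups as well. It ran from 0.025 to 0.097 log2 units per doubling of length in wild type and from -0.13 to -0.052 in the labelled knockouts (exact permutation p = 0.0079, adjusted p = 0.019). With GC and length trends removed, a correction chosen after seeing the data, 4773 of 12542 genes passed, 2331 higher and 2442 lower, and 387 rose and 792 fell at least 2-fold. Of the 6455 called genes with a GC value, 3344 (51.8%) were called in the same direction in both fits, and 27 changed direction.

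**Figure D2:**
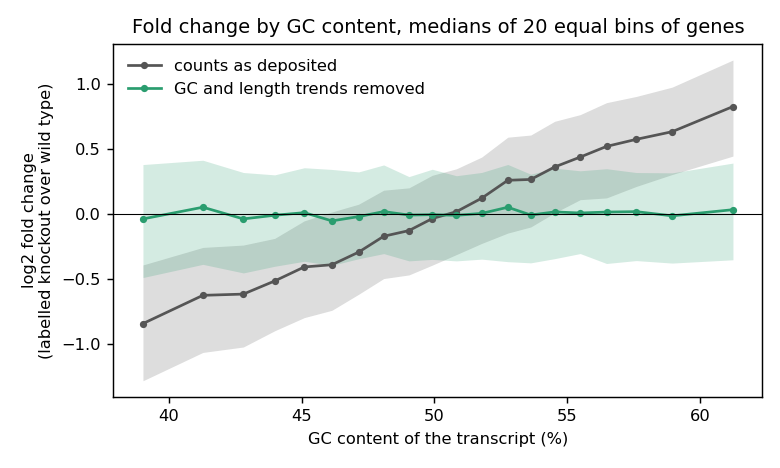
Log2 fold change (labelled knockout over wild type) against transcript GC content in percent, as medians of 20 equal bins of genes with bands from the lower to the upper quartile. Medians climb with GC content in the counts as deposited and lie near 0 in every bin with GC and length trends removed.

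Mitochondrially encoded transcripts were lower in the labelled knockouts. With mRNAs, rRNAs and tRNAs pooled, they took 47.0% ± 11.3 of assigned reads in wild type (SD, n = 5) and 13.3% ± 2.49 in the labelled knockouts (SD, n = 4; exact permutation p = 0.0079, adjusted p = 0.019). The share in single hearts ran from 32.62% (95% Wilson interval 32.60 to 32.64) in WT heart 1 to 58.20% (58.16 to 58.25) in WT heart 2, and from 10.04% (10.02 to 10.05) in KO heart 1 to 15.41% (15.39 to 15.43) in KO heart 4. These intervals cover counting error only. All 13 mitochondrial mRNAs, which encode subunits of the respiratory chain and ATP synthase, fell, both over all genes and adjusted over the list alone, with a median log2 fold change of -2.39. Without both shallow wild-type hearts 12 of the 13 were called lower, with a median of -1.92. The complex I subunit mt-Nd1 fell from 48335 ± 18680 to 5518 ± 727 CPM (log2 fold change -3.13 ± 0.29, edgeR adjusted p = 4.1e-06), and the cytochrome oxidase subunit mt-Co1 fell from 57988 ± 9340 to 15620 ± 1438 CPM (-1.89 ± 0.18, adjusted p = 4.3e-06). The list passed camera (adjusted p = 6.0e-07) but not with an estimated correlation (adjusted p = 0.681). With GC and length trends removed the median was -1.76, mt-Nd1 and mt-Co1 stood at -2.41 and -1.18, 11 of the 13 fell, and the list passed camera (adjusted p = 3.47e-05) but again not with an estimated correlation (adjusted p = 0.962). The ribosomal precursor Rn45s rose in share, from 2.095% ± 1.07 to 4.29% ± 0.367 of assigned reads (exact permutation p = 0.016, adjusted p = 0.028), although its TMM-scaled log2 fold change of 0.51 ± 0.23 did not pass (edgeR adjusted p = 0.073).

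**Figure D3:**
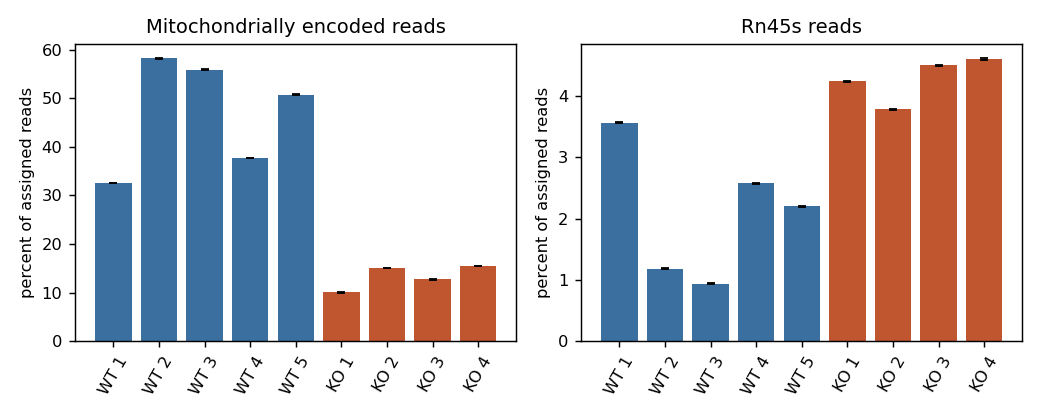
Percent of assigned reads from mitochondrially encoded genes (left) and from Rn45s (right) in each heart, as bars from 0 with 95% Wilson intervals. The 4 labelled knockout hearts lie between 10.04% and 15.41% for mitochondrially encoded reads, below each wild-type heart.

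Nuclear genes for the respiratory chain moved the other way. Of 78 measured members 43 rose and 9 fell (44 and 9 adjusted over the list alone), with a median log2 fold change of 0.52. The ATP synthase subunit Atp5e rose from 54.6 ± 12.1 to 226 ± 17.3 CPM (log2 fold change 2.03 ± 0.15, edgeR adjusted p = 2.0e-06), and the complex I subunits Ndufa2 and Ndufb7 rose by 1.83 and 1.33 on the log2 scale. Atp5e, Ndufa2 and Ndufb7 stood, with the trends removed, at 1.34, 1.43 and 0.39. Uqcrb, a subunit of complex III, fell from 284 ± 58.0 to 47.3 ± 3.85 CPM (-2.58 ± 0.16, adjusted p = 5.9e-07). Camera placed the list higher (adjusted p = 6.0e-05), but not with an estimated correlation (adjusted p = 0.681), nor with GC and length trends removed (adjusted p = 0.083), where 32 rose and 16 fell with a median of 0.20. Glycolytic genes rose in 13 of 21 cases and fell in 2 (14 and 2 adjusted over the list alone), including the phosphofructokinase Pfkl (1.24 ± 0.13), the lactate dehydrogenase Ldha (1.15 ± 0.13) and the hexokinase Hk2 (0.71 ± 0.12). That list passed camera (adjusted p = 0.0047) but not with an estimated correlation (adjusted p = 0.681) or with the trends removed (adjusted p = 0.2995), where 9 rose and 3 fell. Mitochondrial ribosomal proteins rose in 34 of 76 cases and fell in 15 (35 and 15 adjusted over the list alone, 28 and 15 with the trends removed), and the list did not pass camera (adjusted p = 0.074).

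Other metabolic lists were mixed, and none passed camera. Fatty acid oxidation had 7 members higher and 10 lower of 30, and the same adjusted over the list alone (6 and 7 with the trends removed). Etfb, part of the electron carrier for acyl-CoA dehydrogenases, rose (log2 fold change 1.68 ± 0.16), and so did the dehydrogenases Acads (1.39 ± 0.16) and Acadvl (0.96 ± 0.14), while the fatty acid transporter Cd36 fell (-0.98 ± 0.14). With the trends removed Etfb, Acads and Acadvl were at 0.97, 0.65 and 0.66, and Cd36 was at -0.18 and did not pass (adjusted p = 0.242). The tricarboxylic acid cycle had 6 members higher and 6 lower of 19, over all genes and adjusted over the list alone (7 and 3 with the trends removed). Pyruvate carboxylase (Pcx, 1.26 ± 0.16) and Idh2 (0.96 ± 0.14) rose and the succinyl-CoA ligase subunit Sucla2 fell (-1.90 ± 0.25). Mitochondrial biogenesis had 4 higher and 6 lower of 18, again the same adjusted over the list alone (3 and 3 with the trends removed). Ppargc1a, the coactivator that drives it, fell from 128.9 ± 28.7 to 52.3 ± 15.7 CPM (-1.30 ± 0.20, adjusted p = 1.25e-04), the mitochondrial single-stranded DNA-binding protein Ssbp1 fell (-1.70 ± 0.25), and the mitochondrial DNA polymerase Polg rose (1.03 ± 0.13). These 3 stood, with the trends removed, at -0.62, -1.04 and 0.88.

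**Figure D4:**
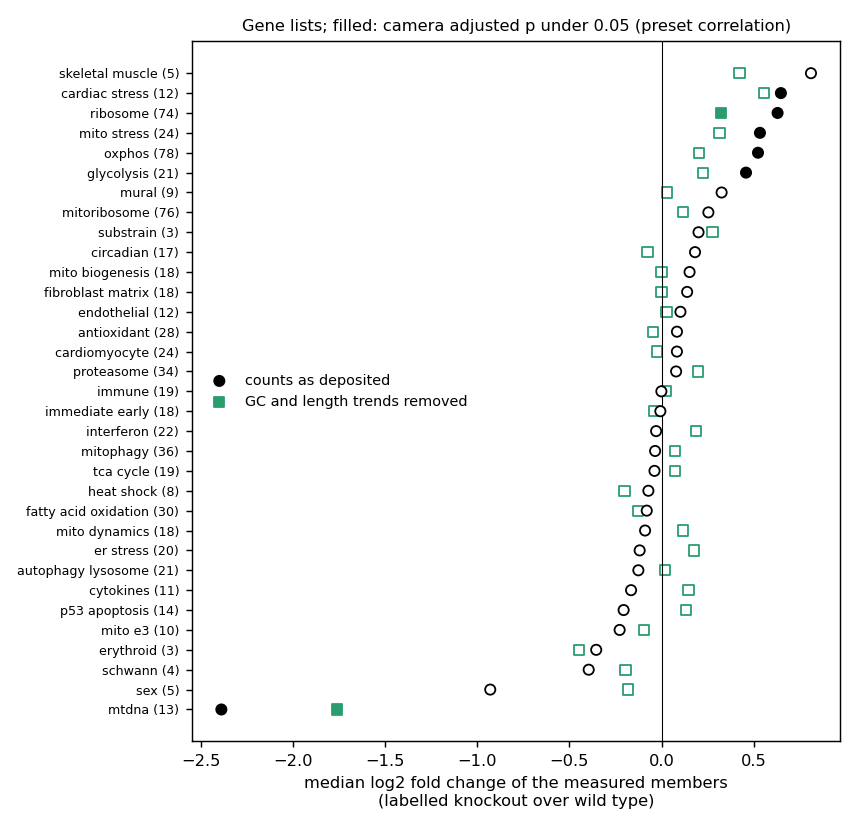
Median log2 fold change of the tested lists reported, with the number of measured members in brackets, from the counts as deposited (circles) and with GC and length trends removed (squares); filled symbols passed camera at an adjusted p under 0.05 with the preset correlation. The 13 mitochondrial mRNAs lie furthest to the left, and they and the ribosomal proteins are filled in both fits.

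Genes of mitophagy did not move as a group. Of 36 measured, 11 rose and 11 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.970), and 6 rose and 9 fell with the trends removed. Pink1, a kinase that marks damaged mitochondria, rose from 328 ± 38.4 to 521 ± 70.5 CPM (log2 fold change 0.67 ± 0.13, edgeR adjusted p = 7.6e-04), but stood at 0.018 with GC and length trends removed (adjusted p = 0.906). The mitofusins, fusion proteins of the outer mitochondrial membrane, were at -0.094 ± 0.15 for Mfn1 (adjusted p = 0.606) and -0.086 ± 0.11 for Mfn2 (adjusted p = 0.536). With the trends removed Mfn2 passed at -0.32 (adjusted p = 0.017), and Mfn1 turned to 0.26 without passing (adjusted p = 0.091). The autophagy receptor Sqstm1 rose (0.89 ± 0.14) and Gabarap, an adaptor of autophagosome formation, fell (-1.15 ± 0.16). Genes of mitochondrial fusion and fission had 5 members higher and 7 lower of 18 (6 and 7 adjusted over the list alone, 3 and 4 with the trends removed), among them the fission factor Mff (-1.23 ± 0.22) and Smcr7 (1.34 ± 0.21). Mitochondrial ubiquitin ligases had 4 higher and 4 lower of 10 (4 and 5 adjusted over the list alone, 1 and 4 with the trends removed), including Huwe1 (-1.11 ± 0.17) and Smurf1 (0.68 ± 0.13). Autophagy and lysosomal genes had 4 higher and 4 lower of 21, also adjusted over the list alone (4 and 7 with the trends removed), with the transcription factor Tfeb higher (1.38 ± 0.17) and the lysosomal membrane protein Lamp2 lower (-1.85 ± 0.22), at 0.53 and -1.08 with the trends removed.

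Transcripts that mark stressed ventricular muscle rose. Of 12 measured, 8 rose and 1 fell (9 and 1 adjusted over the list alone, 8 and 1 with the trends removed). Nppa, encoding atrial natriuretic peptide, rose from 34.9 ± 8.18 to 270 ± 154 CPM (log2 fold change 2.93 ± 0.30, edgeR adjusted p = 8.0e-06), and Nppb, encoding B-type natriuretic peptide, from 55.1 ± 16.5 to 137 ± 53.6 CPM (1.30 ± 0.26, adjusted p = 7.5e-04). Skeletal actin Acta1 rose by 1.66 ± 0.22 and Uchl1, a ubiquitin hydrolase, by 1.73 ± 0.27. Beta-myosin heavy chain Myh7 rose from 697 ± 688 to 3211 ± 1116 CPM (2.21 ± 0.58, adjusted p = 0.0052). Its wild-type values were uneven, at 169, 235 and 183 CPM in WT hearts 1, 2 and 4 and 1408 and 1491 in WT hearts 3 and 5. In FPKM, WT hearts 1 to 5 had 582, 324, 590, 439 and 710, without such a gap. The Myh7 locus overlaps Mhrt and Mir208b. Xirp2, an actin-binding protein of the intercalated disc, fell (-1.27 ± 0.16). The FPKM table lists Xirp2 at 0 in WT hearts 1, 2 and 4 and KO heart 1. Its fold change there was 1.36 ± 1.44 and did not pass (limma adjusted p = 0.443). With the trends removed Nppa, Nppb, Myh7 and Acta1 stayed higher, at 2.33, 1.33, 1.76 and 1.07, and Uchl1 and Xirp2 stood at 1.13 and -0.58. The list passed camera (adjusted p = 0.034), but not with an estimated correlation (adjusted p = 0.657) or with the trends removed (adjusted p = 0.096). Cardiomyocyte markers had 9 members higher and 5 lower of 24 (10 and 5 adjusted over the list alone, 5 and 3 with the trends removed; camera adjusted p = 0.970), with the light chain Myl3 (1.24 ± 0.14) and Mybpc3 (1.05 ± 0.17) higher and phospholamban, Pln, lower (-1.43 ± 0.13), at 0.67, 0.56 and -0.63 with the trends removed. Fast skeletal Myh2 and Myh4 were called higher at 3.82 ± 0.59 and 1.76 ± 0.43, but they share sequence with other myosins. Without WT heart 5 Myh2 stood at 5.11. Myh2 received 0 to 2.26 reads per 1000 Myh7 reads in wild-type hearts and 3.55 to 5.30 in the labelled knockouts. The skeletal muscle list as a whole, with 3 of 5 higher, also adjusted over the list alone (3 higher and 1 lower with the trends removed), did not pass camera (adjusted p = 0.385).

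Ribosomal protein genes rose. Of 74 measured, 50 rose and 7 fell (51 and 9 adjusted over the list alone), with a median log2 fold change of 0.63 (camera adjusted p = 3.0e-07; adjusted p = 0.360 with an estimated correlation). Rpl8 (2.12 ± 0.18), Rps14 (2.04 ± 0.19) and Rps18 (1.64 ± 0.14) were among them, while counts of this family are uncertain because processed pseudogenes share its sequence. With the trends removed these 3 stood at 1.38, 1.38 and 1.02, 36 rose and 9 fell, and the list still passed camera (adjusted p = 8.4e-05), but not with an estimated correlation (adjusted p = 0.453). Genes of the mitochondrial stress response had 12 of 24 higher and 1 lower, also adjusted over the list alone (camera adjusted p = 0.010), and the list did not pass with an estimated correlation (adjusted p = 0.404). Its higher members included the transcription factors Cebpb (1.88 ± 0.26) and Ddit3 (1.04 ± 0.15), the mitochondrial protease Lonp1 (0.81 ± 0.12) and the proline synthesis enzyme Aldh18a1 (1.17 ± 0.19), which stood at 0.86, 0.45, 0.28 and 0.88 with the trends removed. That list did not pass with the trends removed either (adjusted p = 0.2995), where 10 rose and 2 fell. It also missed the threshold with nuclear counts thinned to equal depth, where its median was 0.37.

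None of the remaining stress lists passed camera. Endoplasmic reticulum stress had 6 higher and 4 lower of 20 (5 and 4 adjusted over the list alone, 6 and 3 with the trends removed), with Creld2 at 1.30 ± 0.20 and the chaperone Dnajb9 at -1.73 ± 0.32 (0.87 and -0.9995 with the trends removed). Antioxidant genes had 10 higher and 10 lower of 28, also adjusted over the list alone (7 and 9 with the trends removed). Among them the peroxiredoxin Prdx5 rose (1.26 ± 0.16) and extracellular superoxide dismutase Sod3 fell from 140 ± 49.2 to 30.5 ± 7.01 CPM (-2.19 ± 0.23, adjusted p = 8.9e-06), at 0.56 and -2.42 with the trends removed. Heat shock genes had 3 higher and 2 lower of 8, also adjusted over the list alone (1 and 3 with the trends removed). The small heat shock protein Cryab fell (-0.68 ± 0.16). Hsp90aa1 (-0.35 ± 0.13), Hspb1 (0.56 ± 0.18) and Hspb7 (0.45 ± 0.15) were called too, but each lost its call without WT heart 4 and turned direction with the trends removed, where Hspb1 passed as lower (-0.41, adjusted p = 0.047). The proteasome had 13 higher and 6 lower of 34, also adjusted over the list alone (12 and 6 with the trends removed), and did not pass camera (adjusted p = 0.385). Psmb5 was at 1.70 ± 0.14, or 1.05 with the trends removed. The p53 and apoptosis list had 3 higher and 4 lower of 14, also adjusted over the list alone (0 and 4 with the trends removed), with Bak1 at -0.80 ± 0.16 and Bax at 1.47 ± 0.18. Bax did not pass with the trends removed (0.48, adjusted p = 0.053).

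Markers of other cell types showed no shared direction by camera. Fibroblast and matrix genes had 7 higher and 5 lower of 18 (8 and 5 adjusted over the list alone, 2 and 4 with the trends removed), with the small proteoglycans Lum (-2.12 ± 0.29), Dcn (-1.21 ± 0.23) and Bgn (-0.83 ± 0.16) lower, at -1.50, -0.70 and -1.01 with the trends removed. Endothelial markers had 5 higher and 2 lower of 12, also adjusted over the list alone (3 and 2 with the trends removed), such as Egfl7 (1.12 ± 0.15, 0.45 with the trends removed) and Emcn (-0.72 ± 0.14), which did not pass with the trends removed (-0.054, adjusted p = 0.783). Mural cell markers had 3 higher and 2 lower of 9 (4 and 2 adjusted over the list alone, 2 and 0 with the trends removed), with Cspg4 at 1.31 ± 0.17 (0.69 with the trends removed). Immune markers had 4 higher and 3 lower of 19 (2 and 3 adjusted over the list alone, 0 and 6 with the trends removed), with C1qa, a complement component, at 0.89 ± 0.20 and Cd68, a macrophage marker, at -1.04 ± 0.22. C1qa did not pass with the trends removed (0.071, adjusted p = 0.741). Of 3 erythroid markers Fech was lower (-0.41 ± 0.13), but it did not pass with the trends removed (adjusted p = 0.966). The adipocyte list had 2 measured members, Fabp4 at 243 and Cidea at 26.4 CPM in the labelled knockouts against 291 and 23.5 in wild type, and neither passed. With the trends removed Cidea passed as lower (-0.42, adjusted p = 0.023). Of the atrial list 2 members were measured, of which Nppa rose.

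Interferon-response genes had 5 higher and 5 lower of 22 (4 and 2 with the trends removed), with Ifi27l2a at 2.16 ± 0.35 and Tmem173, which encodes the adaptor STING, at -0.97 ± 0.19. Among 11 cytokine and adhesion genes Icam1 rose (0.62 ± 0.18) and the chemokine Cxcl9 fell (-1.72 ± 0.25), and 0 and 2 were higher and lower with the trends removed. Icam1 did not pass with the trends removed (0.22, adjusted p = 0.288). Circadian genes had 6 higher and 7 lower of 17 (3 and 6 with the trends removed), with Clock itself at -1.63 ± 0.17 (-0.88 with the trends removed) and its output gene Dbp at 0.96 ± 0.11, which was 0.16 with the trends removed (adjusted p = 0.257). Immediate-early genes had 5 higher and 5 lower of 18 (1 and 5 with the trends removed), with Egr1 at -1.37 ± 0.28 and Junb at 1.55 ± 0.36. Junb did not pass with the trends removed (0.69, adjusted p = 0.081). Counts over all genes were the same adjusted over each list alone, and none of these lists passed camera. In a list of genes known to vary between mouse strains, Nnt, the nicotinamide nucleotide transhydrogenase, had 351 ± 89.0 CPM in wild type and 405 ± 58.6 CPM in the labelled knockouts (adjusted p = 0.330), and Ide was lower (-1.01 ± 0.19), 1 of 3 measured (1 higher and 1 lower with the trends removed). The sex-linked list had 3 of 5 lower, also adjusted over the list alone (camera adjusted p = 0.218), and 1 higher and 0 lower with the trends removed.

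The largest rises with groups that did not overlap included Tmem38b, which encodes the TRIC-B cation channel of intracellular membranes (chromosome 4, 53825988 to 53862019). It rose from 18.7 ± 5.74 to 155 ± 37.3 CPM (log2 fold change 2.998 ± 0.22, edgeR adjusted p = 2.0e-06). The neurotrophic factor Nrtn (2.87 ± 0.41), the uncharacterised Gm10653 (2.87 ± 0.32), Rpl36 (2.38 ± 0.27), Col11a2 (2.33 ± 0.41) and 1810043H04Rik (2.32 ± 0.35) rose as well. Tmem38b stood, with the trends removed, at 3.68 and these 5 at 1.49, 2.40, 1.30, 1.51 and 1.71. Gm10653 overlaps Cln6 and Calml4. Myh2, Nppa and Dnahc8, given elsewhere, completed the list. The small nucleolar RNAs Snord83b, Snord22 and Snord55 were also among them and lie within longer genes, whose reads cannot be told apart from theirs. Snord55 had 1 read over all wild-type hearts and 41 to 111 reads in each labelled knockout. The largest falls included Wdr92 (chromosome 11, 17211893 to 17235200), from 299 ± 119 to 25.1 ± 8.61 CPM (-3.58 ± 0.32, adjusted p = 4.1e-06). The chromatin protein gene Hmga2 fell by 3.42 on the log2 scale and the lipase Lipi by 4.43. The zinc finger genes Zfp37 and Zfp963 fell by 3.74 and 3.62. The values of Wdr92, Hmga2, Lipi, Zfp37 and Zfp963 with the trends removed were -3.24, -3.06, -3.66, -2.95 and -3.10. Psg28, Smok4a, Vmn2r55, Gm5615, AU023762 and Snord82 fell too, with log2 fold changes from -5.05 for Psg28 to -3.48 for AU023762 (-4.74 and -2.77 with the trends removed). Their counts are uncertain, since Snord82 lies within Ncl, Smok4a overlaps 2700054A10Rik, AU023762 overlaps Gm7183, and Psg28, Smok4a and Vmn2r55 belong to families of similar genes. An entry named by a date, 4-Mar, also fell (-5.12 ± 0.81), and its gene was not resolved. It had 24, 43, 36, 28 and 47 reads in WT hearts 1 to 5, which did not rise with the read total. Its CPM was therefore 1.08 in WT heart 1 and 14.9 in WT heart 2. Wild-type reads of Gm5615 (29 to 43) and AU023762 (17 to 24) did not rise with the read total either. Several of these falls were smaller with hearts left out. Without both shallow wild-type hearts 4-Mar, Gm5615, AU023762, Smok4a, Vmn2r55 and Zfp37 stood at -4.02, -3.20, -2.59, -3.31, -2.77 and -2.79, and without WT heart 5 Snord82 stood at -3.44. Other falls were larger, with Lipi at -5.41 without KO heart 1 and Smok4a at -4.59 without KO heart 3.

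On chromosome 17, 3 adjacent genes rose, of which Btbd9 and Glo1 were chosen after their values were seen. Btbd9 (30215524 to 30582621) rose by 0.90 ± 0.13, the glyoxalase Glo1 (30592861 to 30612659) from 40.2 ± 2.34 to 118 ± 36.4 CPM (1.55 ± 0.17, adjusted p = 1.0e-05), and the dynein heavy chain Dnahc8 (30626935 to 30875762) by 2.70 ± 0.34. With the trends removed they stood at 0.63, 1.97 and 2.98.

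The FPKM table gave a similar ranking of genes and another balance of directions. Limma-trend called 6730 of 12637 genes, 5961 higher and 769 lower, with a median log2 fold change of 0.44, so that 88.6% of calls were higher. With each heart centred on its median, 3033 were higher and 3869 lower (43.9% higher). Among 11831 genes tested in both tables, 3919 were called in the same direction and 16 in opposite directions, while 2344 were called from the counts alone and 2481 from FPKM alone. Fold changes of both tables correlated across genes with a Spearman rho of 0.95. Nppa rose from 47.0 ± 18.8 to 515 ± 269 FPKM (log2 fold change 3.38 ± 0.38, limma adjusted p = 2.4e-04), and Glo1 from 26.8 ± 6.82 to 124 ± 46.7 FPKM (2.13 ± 0.26, adjusted p = 2.5e-04). In that table mt-Nd4 and mt-Nd4l are listed at 0 in WT hearts 1 and 5, and mt-Co1 and mt-Ts1 in WT heart 1, so those values were not compared. The other mitochondrial mRNAs were called lower from FPKM, except mt-Nd3 (-0.29, limma adjusted p = 0.385). Of these mt-Co3 passed narrowly (-0.66, limma adjusted p = 0.048). Some mitochondrial tRNAs were not lower, such as mt-Tc (0.65, limma adjusted p = 0.106).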

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

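The GC and length correction and thinning were chosen after seeing the data, and the tests of the GC trend on the breadth of the difference, of cardiomyocyte loss, of RNA carry-over and of the Btbd9, Glo1 and Dnahc8 run were chosen after those results were seen. The other tests were written down before their results were seen.

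Between the genotypes 6503 genes were called. In only 1 of 100 splits of the hearts into 4 and 5, the real one, were as many called (highest other 4580, WT hearts 2 to 5 against WT heart 1 and the labelled knockouts). The same held after the GC and length correction (1 of 100, 4773 against 3149). The real split is always counted, so 1 of 100 is the smallest share possible. Without the correction only 5 splits called any gene, and each kept the labelled knockouts in 1 group. The splits thus argue against chance but cannot exclude it. With the GC and length trend removed, 51.8% of called genes were still called in the same direction. The bound of 50% was set after the result was seen and lies close to this share. Passing it therefore decides nothing about the trend as the whole cause. The calls kept did not need the fitted trend, and the remaining calls may rest on it. Depth is argued against as the whole cause, since thinning nuclear reads to 1845431 per heart left 75.4% as many calls. A harvest or library batch that coincides with genotype cannot be told apart from it, because 0 labels name a batch, date or run, and an effect of genotype stays open beside it. The counts gave no independent evidence for the genotype labels, so every direction depends on the labels being right.

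Mitochondrially encoded mRNAs fell in the labelled knockouts with a median log2 fold change of -2.39. The GC and length trend is argued against as the whole cause, since the median stayed at -1.76 without it. Fewer cardiomyocytes would lower the markers of these cells by about as much, and their median was 0.083. Less carry-over of RNA without a long poly(A) tail would lower Rn45s, whose log2 fold change was 0.51 ± 0.23. Rn45s is a nuclear ribosomal precursor, so its value cannot decide how well mitochondrial RNA was captured. Among wild-type hearts the share of mitochondrial reads fell as the read total rose, and the cause of that was not tested. A difference in mitochondrial transcripts with genotype and a difference in their capture stay open as possible explanations. So does a batch that coincides with genotype, for which 0 labels give a test.

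Btbd9, Glo1 and Dnahc8 were higher together. All 3 were still called with the GC and length trend removed. Only 0.0080% of 12464 runs of 3 neighbouring genes were as high, but the run was picked from these runs, so its rank decides nothing about chance. A candidate explanation is a segment of donor-strain chromosome, such as a copy-number difference. It stays open, since the median of -0.0070 (SD 0.48) of the 20 flanking genes within 1 Mb decides nothing about genes picked for being high, and no genotype was read here.

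Single hearts stood apart from the others of their group in 23 of 322 sets of values, where chance alone gives about 1 in 20 groups, or 16.1. The values were not corrected for GC content. KO heart 4 had the steepest GC slope of all hearts (0.65 log2 units per 10 percentage points), and KO heart 1 the lowest of the labelled knockouts (0.17). KO heart 4 was the highest of its group for Bbc3 (3.79 CPM), C1qa (54.3), Egr1 (32.8), Hspb1 (393), Junb (22.0), Psmb10 (48.1), Tfeb (39.7) and Uchl1 (10.8). KO heart 1 was the lowest for Cxcl9 (2.09 CPM), Dnajb11 (29.0), Esam (46.4) and Txnrd2 (19.1), and the highest for Hlf (42.4) and Sucla2 (119.7). KO heart 3 was the highest for Snord55 (5.61 CPM). WT heart 1 was the highest for Pgam2 (303.2 CPM), Psmb5 (17.6), Sqstm1 (219) and Snord55 (0.045), WT heart 3 for Oasl2 (17.5) and Phlda3 (4.74), and WT heart 5 for Gm10653 (1.28) and Snord82 (53.04).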

How the results depend on the processing

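The GC and length correction, the omission of mitochondrially encoded genes and Rn45s or of the 2 shallow wild-type hearts, thinning and median-centred FPKM were chosen after seeing the data; the other alternatives were fixed before the data were examined. The count of changed genes stayed within 1.5 times of 6503 under all of these settings but 1, from 4773 with the correction to 7535 at a threshold of 0.1, and from 5594 to 6752 with single hearts left out. Without both shallow wild-type hearts it was 5827, and 4038 with the correction as well. The labels do not say that numbers pair hearts, and deviations of same-numbered hearts correlated at -0.26 to 0.04. These deviations still hold each heart's GC and length trends, so they cannot decide whether hearts were paired. With a replicate block 5030 genes, 6 lists and 5306 genes from FPKM were called. Knockout hearts correlated best with their own number in 1 of 4 cases. Of 6 lists called, 0 passed with an estimated correlation, 2 with the correction (with or without the shallow hearts), and 6 with fry, which called 10 of the 34 tested lists. The others that fry called were the sex-linked list as lower (fry adjusted p = 0.0048), and skeletal muscle (0.010), mitochondrial ribosomal proteins (0.013) and the proteasome (0.038) as higher. Fry was run without the correction only. As many lists as in the real grouping passed in 25 of 100 splits, up to 11, so chance cannot be excluded for the number of lists. In 69 of the 100 splits no gene was called, yet at least 1 list passed camera with the preset correlation. Passing it therefore does not by itself exclude chance for a single list. Oxidative phosphorylation, glycolysis, mitochondrial stress and cardiac stress were the lists lost with the correction, and the cause was not tested beyond it.

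FPKM calls ranged from 5643 to 7353 with single hearts left out; 2 of 100 splits gave as many as 6730, the other being WT hearts 2 to 5 against the rest with 6999.

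Log2 fold changes of named genes that turned sign with the correction were Cidea -0.42, Fabp4 0.29, Hsp90aa1 0.19, Hspb1 -0.41, Hspb7 -0.10, Mfn1 0.26, Rgs5 0.028, Stub1 -0.075 and Uty 0.78, of which Cidea, Hspb1 and Uty passed in the new direction. Without both shallow hearts as well they were Cidea -0.53, Fabp4 0.39, Hsp90aa1 0.24, Hspb1 -0.31, Hspb7 -0.13, Kdm5d 0.038, Mfn1 0.21, Pink1 -0.059, Rgs5 0.013, Stub1 -0.054, Uty 0.68 and Xist 0.29, of which Cidea and Uty passed. Cidea was -0.0097 without the shallow hearts alone, and Mfn1 ranged from -0.20 to 0.051 with single hearts left out, the highest without KO heart 4. Single hearts left out ended calls of Cd79a, Emr1, Hsp90aa1, Hspb1, Hspb7 and Kdm5d, and Xist passed without WT heart 5. Over all settings, named genes lost the call in 74 gene and setting pairs, gained it in 4 and kept direction and side of the threshold in 3127. Depth limits genes of few reads, as Xist had 2 to 21.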
